A study of Mus musculus with 32 samples.

How the data were processed

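Poly(A) RNA of inguinal fat, perigonadal fat and liver was prepared with Trizol and RNeasy columns and a TruSeq Stranded mRNA kit, per the labels' protocols. The submitters' processing notes name STAR, DESeq2 and the build mm10 without versions. The read counter, its strand setting and the gene annotation are not given in the sources used here, so overlapping, antisense and near-identical genes may share reads. Samples were grouped by the labels into 8 groups of 4, and replicate numbers are the labels'. For 1 AKO liver sample (replicate 4) the description names WT perigonadal fat while the title, tissue and genotype say AKO liver, and the title was followed. The labels give separate animal numbers within each group.

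The deposited count tables hold whole-number read counts per gene and library, not normalized, for male inguinal fat, female inguinal fat and male liver (24 samples). They were found to hold only the genes in the authors' lists: 1074, 790 and 34 genes. The authors' deposited tables of comparisons hold a mean of normalized counts (a signal on the scale of counts, per the file headers), a log2 fold change with its standard error, a p-value and an adjusted p-value, per the file headers. The liver table holds no p-value apart from the adjusted one and its values are rounded. Every listed adjusted p is under 0.05. No counts for perigonadal fat were used here. The deposited log2 fold has the sign of AKO over WT in all 1074, 790 and 34 genes with counts, and for perigonadal fat the same direction is assumed, as its column is named alike. Deposited log2 folds rose with a slope of 0.791, 0.753 and 0.711 on the plain log2 ratios, so they are shrunken there (male inguinal fat, female inguinal fat and liver), which was not measured for perigonadal fat. Counts of the liver table held 3 repeated rows, which were left out, and 3 listed liver genes had no counts. A female gene name that a spreadsheet had turned into a date was restored by its mean, and 3 perigonadal names could not be.

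The authors' size factors were solved by least squares from the counts and the deposited means. The largest misfit was 4.73e-08% (female), 4.79e-08% (male) and 0.298% (liver, where means are rounded). They served as offsets. The number of genes the authors tested was recovered from p and adjusted p (12554, 13546 and 13361 for male inguinal, female inguinal and perigonadal fat) and estimated for liver (11441). Counts were tested with edgeR 4.0.16 (glmQLFit in its legacy mode and glmQLFTest, quasi-likelihood) in R 4.3.3, WT against AKO within each tissue and sex, with no covariate, no filter and Benjamini-Hochberg adjustment at 0.05, over the list alone and over the number of genes tested. Standard errors are the log2 fold divided by the root of the F statistic. Folds of genes with counts are those of the edgeR fit unless credited to the authors, and can differ from the ratio of the group means. Sex by genotype was tested over the 290 genes held for both sexes and 16 libraries. For its arrangements of the sex labels, the mean of each sex was removed from each gene's log2 values and the labels were then exchanged within genotype. The 22 gene lists were fixed before the data were examined, as were the design, the alternative settings and the rule for named genes. Each list with at least 3 called genes in a table was compared in direction with the other called genes by Fisher's exact test. That test counts genes as independent trials, so its p does not measure the spread between mice. Enrichment was not tested, since uncalled genes are not held. The lists cover growth hormone signalling, fatty acid synthesis, triglyceride storage, lipolysis, thermogenesis and oxidation, adipocyte identity, insulin signalling, matrix, growth factors, cytokines, cholesterol, liver sex-biased genes, the clock, the cell cycle, and markers of progenitors, macrophages, lymphoid, endothelial or mural, epithelial, muscle, Schwann or neuronal, and erythroid, granulocyte or mast cells.

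Named genes are Bcl6 and Adipoq wherever listed, the 10 largest rises and 10 largest falls per table by the authors' fold among genes with a mean of at least 50 and, with counts, no overlap between WT and AKO (names Gm and a number or ending in Rik left out), up to 4 members of each list per table by lowest adjusted p, and the 10 genes with the largest smallest change among those called in one direction in all 3 adipose tables. Every gene of the liver table would have been named at 30 or fewer. Further list members, and genes that make up a count of 5 or fewer, are named to complete that count, after their values were seen. Results of some genes, and of the Schwann or neuronal list, are not reported here. Old symbols are kept as in the files. Positions are from GENCODE M21 (GRCm38, the assembly of mm10), which placed 1065 of 1074, 784 of 790, 1473 of 1488 and 37 of 37 genes of male inguinal, female inguinal, perigonadal fat and liver, through synonyms where needed.

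All pairs of libraries within a group differed by more than sampling noise (lowest chi-square per degree of freedom 7.41). The edgeR step was tested on simulated counts for the 1074 male inguinal, 790 female inguinal and 34 liver genes. Of genes changed by a log2 fold of 0.5 it recovered 87% of 100, 70.4% of 98 and 80% of 5. It recovered all genes changed by a log2 fold of 1. Every simulated gene of a table had the same dispersion, fitted on the called genes, so differences in noise between genes were not simulated. Alternatives were TMM, the total of the table, median-of-ratios scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1), filterByExpr, a replicate block, leaving out each library, a fold of at least 1.5, stricter thresholds on the authors' adjusted p and a mean of at least 100. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps. A p from 4 against 4 libraries in an exact permutation test cannot go below 0.0286.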

Results

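Poly(A) RNA was sequenced from tissues of C57BL/6 mice that carried loxP-flanked Bcl6 alleles, either without Cre (WT) or with Cre under the adiponectin promoter (AKO, adipocyte knockout). No group carried Cre without loxP-flanked Bcl6, so effects of the deletion cannot be told apart from those of Cre or its transgene. Bcl6 encodes a zinc-finger transcriptional repressor, and the series aimed to find the adipocyte genes it regulates. The 32 samples fell into 8 groups of 4: WT and AKO inguinal fat of males, inguinal fat of females, perigonadal fat of males and liver of males. By the animal numbers in the labels, male inguinal and perigonadal fat came from the same mice and liver from others. Counts per library were analysed for inguinal fat and liver, and only for genes the authors had called. The counts in those genes ran from 592820 to 2603509 per library in male inguinal fat, from 864592 to 4072659 in female inguinal fat and from 97314 to 358660 in liver. These totals are not sequencing depth, and the depth of the whole libraries is unknown. The authors' size factors, recovered from their mean counts, show relative depth. In females they averaged 0.786 ± 0.285 in WT and 1.37 ± 0.233 in AKO (SD, n = 4 each, two-sided exact permutation test, p = 0.0286). In males they averaged 0.838 ± 0.332 and 1.36 ± 0.423 in inguinal fat (exact permutation p = 0.143) and 1.08 ± 0.751 and 1.10 ± 0.286 in liver (exact permutation p = 0.686). No perigonadal counts were analysed here, and values for that depot are the authors'.

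The targeted gene was measured in every female inguinal library. Bcl6 (mm10, chromosome 16, 23965052 to 23988852, minus strand) had normalized counts of 1442, 1176, 988 and 1004 in the WT libraries and 2618, 2295, 2800 and 2555 in the libraries labelled AKO. The edgeR fit put Bcl6 2.24-fold higher in AKO (log2 fold 1.16 ± 0.12 SE, edgeR adjusted p = 4.76e-05 over the list alone). The counts cover the whole gene and do not separate recombined exons from the rest, so they do not check the genotype labels, and AKO below means the libraries labelled so. Bcl6 was not among the genes listed for male inguinal fat, perigonadal fat or liver. Adipoq, whose promoter drives Cre (chromosome 16, 23146536 to 23158028), was 1.40-fold higher in female AKO libraries, at 66846 ± 5567 against 47614 ± 2527 normalized counts (SD, n = 4).

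In male inguinal fat, the comparison asked which genes differ when Bcl6 is targeted in adipocytes. Mfsd7c, a membrane transporter gene on chromosome 12 (85746539 to 85813585), rose 17.6-fold, from 25 ± 4.23 normalized counts in WT to 437 ± 14.1 in AKO (SD, n = 4; log2 fold 4.14 ± 0.12 SE). Rgs16, a regulator of G-protein signalling, rose 10.1-fold, from 41.2 ± 9.88 to 416 ± 91.6. Nt5e, which encodes the ectonucleotidase CD73, rose 7.32-fold, Srgap3 6.09-fold, and Spon1, a secreted matrix protein gene, 5.53-fold. The imprinted gene Peg3 rose 7.41-fold and the imprinted growth factor gene Igf2 5.55-fold, from 270 ± 62.8 to 1501 ± 46.9. Gpr179 and Mmd2 rose from WT levels near the floor. Gpr179 had 4 raw counts over the 4 WT libraries and 762 over the 4 AKO libraries, and Mmd2 had 32 and 738. Among the falls, Pon1 (paraoxonase) was 5.75-fold lower (236 ± 28.3 against 40.3 ± 4.56), Rprml 5.46-fold, Sctr (secretin receptor) 3.79-fold, Ncan 3.62-fold and Klhl2 3.37-fold lower. Net1, a guanine nucleotide exchange factor gene, fell from 6309 ± 824 to 2317 ± 451. Lrp3, Slc2a13, Odf3l1 and Kctd15 fell by 1.40, 1.38, 1.24 and 1.12 on the log2 scale. As the rule for naming these genes required, the 4 WT and 4 AKO libraries did not overlap. The edgeR adjusted p over the list alone ran from 2.93e-09 (Mfsd7c) to 0.00259 (Ncan).

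Grouped by the gene lists, 11 of the 12 called extracellular matrix genes rose in male inguinal fat (Fisher's exact test, two-sided, against 52.6% of the other called genes, p = 0.00717, adjusted p = 0.0464). Examples are Col12a1, up 2.50-fold, Thbs2, up 1.91-fold, Col6a1, up 1.58-fold, and the basement membrane gene Nid1, up 1.57-fold. All 8 called growth factor genes rose (Fisher's exact test, p = 0.00843, adjusted p = 0.0464), among them Igf2, Angpt1 (1.49-fold), Bmp2 (1.57-fold) and Bdnf (3.17-fold, from 10.8 ± 4.86 to 35.5 ± 5.36 normalized counts). At the authors' adjusted p under 0.01 neither list passed (adjusted p = 0.355 for matrix and 0.289 for growth factors). Here and in the other tables, the list tests count genes of the same libraries as independent trials. Their p does not measure the spread between mice. The other 9 lists with at least 3 called genes did not differ in direction from the rest, with adjusted p from 0.23 to 0.69. Within these, 5 of 6 triglyceride storage genes fell, including Bscl2 (log2 fold -0.43 ± 0.08 SE) and Vldlr (-0.60 ± 0.10), while Fabp5 rose 1.57-fold. All 3 called genes of the lipolysis list fell: Pnpla2, the adipose triglyceride lipase gene, from 44770 ± 5245 to 29441 ± 3787, Adora1 1.67-fold and Adrb1 1.62-fold. That list does not separate genes that promote lipolysis from genes that restrain it. Of the 6 oxidation and thermogenic genes 5 fell, such as Acadl (-0.72 ± 0.15) and Kcnk3 (-0.62 ± 0.11), and Acot2 rose 1.77-fold. Of 6 fatty acid synthesis genes 5 rose, led by the desaturase genes Fads1 (2.92-fold) and Fads2 (2.00-fold), while the lipogenic regulator gene Srebf1 fell 1.82-fold. Of the adipocyte identity genes 1 rose (Ebf1, 1.67-fold) and 3 fell (Rxra, Plin1 and Cebpa). Of the insulin signalling genes 4 rose, such as Akt1 (1.48-fold), and 2 fell, such as Akt2 (1.28-fold). All 3 called members of the cell cycle list (Ccnd2, 1.89-fold, Cdkn2c and Ccnd3), of the cytokine list (Cxcl9, 1.49-fold, Ccl11 and Orm2) and of the cholesterol list (Sc5d, Mvd and Dhcr7) rose. Lists with fewer called genes were not tested. Socs2 (2.86-fold) and Igfbp4 of the growth hormone list rose, and the clock genes Dbp and Nr1d2 fell. Of the lists for other cells, Lrrn4, Esr1 and Pecam1 rose and Cd14, Cspg4 and Acta1 fell, and which cells expressed them was not tested.

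The authors listed 1074 genes for this comparison, 570 higher and 504 lower in AKO, of 12554 tested. The edgeR quasi-likelihood test called 569 higher and 503 lower when adjusted over the list alone, which is not independent evidence because the genes were chosen on these samples. Adjusted over all 12554 genes it called 366 higher and 285 lower.

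In female inguinal fat, several of the largest changes were in genes already named for males. Rgs16 rose 7.28-fold, Mfsd7c 7.14-fold and Nt5e 4.60-fold, the last from 277 ± 48.0 to 1261 ± 75.1 normalized counts (SD, n = 4). Kcnj15, a potassium channel gene, rose 8.86-fold, from 251 ± 55.8 to 2225 ± 282. The Krüppel-like factor gene Klf14 (chromosome 6, 30956023 to 30959078) rose 10.3-fold in the edgeR fit. The glucagon receptor gene Gcgr rose 10.2-fold in that fit, with group means of 28.2 ± 13.4 in WT and 312 ± 128 in AKO. Arhgef37 rose 5.54-fold and Slc15a5 5.46-fold. Gpr179 had 14 raw counts over the 4 WT and 989 over the 4 AKO libraries. Sctr was 6.06-fold lower in AKO, Acsm3, an acyl-CoA synthetase gene, 5.26-fold, Pon1 4.67-fold, the transferrin receptor 2 gene Tfr2 4.36-fold, Lrtm1 3.07-fold and Klhl2 2.78-fold lower. Rhbdl2, Aldh3b2, Rgs7 and the keratin gene Krt8 fell by 1.36, 1.31, 1.31 and 1.19 on the log2 scale. The edgeR adjusted p over the list alone ran from 3.50e-07 (Rgs16 and Mfsd7c) to 0.00171 (Lrtm1), and WT and AKO libraries did not overlap, as the rule for naming these genes required.

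None of the 12 tested lists differed in direction from the other called female genes after adjustment. The lowest adjusted p by Fisher's exact test was 0.111, for 7 of 7 extracellular matrix genes higher in AKO (p = 0.0184) and 5 of 5 epithelial markers lower (p = 0.0183). The matrix genes included the metalloproteinase genes Mmp12, up 5.59-fold from 55.8 ± 16.3 to 304 ± 105, and Mmp9, up 1.78-fold, and Col6a1, up 1.58-fold. The epithelial markers were Krt8 (10167 ± 1392 against 4463 ± 904), Krt7 (log2 fold -1.21 ± 0.17 SE), the milk protein gene Csn3 (-0.66 ± 0.13), Cldn7 (-0.76 ± 0.19) and Trps1. All 5 called macrophage markers rose (adjusted p = 0.271), including Mmp12, which the matrix list also holds, Cd163 (1.67-fold), Csf1r (1.44-fold) and Lyz2 (1.32-fold). All 4 called cell cycle genes rose (adjusted p = 0.394), led by the cyclin-dependent kinase inhibitor gene Cdkn1c (3.58-fold, 828 ± 156 against 2951 ± 690). Fatty acid synthesis genes went both ways (4 higher, 5 lower): Fads1 and Fads3 rose 1.87-fold and 1.75-fold, and the acetoacetyl-CoA synthetase gene Aacs fell 2.03-fold. Of 5 triglyceride storage genes 4 fell, led by Slc27a2 (3.48-fold) and Plin5 (2.04-fold), and the lipoprotein lipase gene Lpl rose 1.33-fold. Of the oxidation and thermogenic genes 3 rose, among them Acot2, 1.86-fold, and 4 fell, among them Ehhadh, 1.48-fold. Of the lipolysis genes Prkar2b rose 1.46-fold and Adora1 and Adrb3 fell. Of the growth factor genes 4 rose, including Bmp3 (2.17-fold) and Fgf13 (2.02-fold), and 2 fell, including Igf1 (1.41-fold), which the growth hormone list also holds beside Igfbp4 (up 1.41-fold). The insulin signalling genes Insr, Akt1 and Foxo1 rose 1.23-fold to 1.38-fold. Adipocyte identity genes were 3 higher (Adipoq, Lpl and Sfrp5, the last 1.72-fold) and 1 lower (Rxra). Of the cytokine list 3 rose, such as Ccl11 (1.69-fold) and Orm2, and 3 fell, such as the haptoglobin gene Hp (2.09-fold) and Cxcl14. Lists with a single called gene were the clock (Bhlhe41, lower), progenitor (Lrrn4, higher), mural (Cspg4, lower) and muscle lists (Car3, higher). Car3 had the highest mean of the listed female genes, 286036 normalized counts, above Adipoq at 57230. Its rise therefore cannot be read as a change in muscle cells.

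For females the authors listed 790 genes of 13546 tested, 434 higher and 356 lower in AKO. The edgeR test adjusted over the list alone called the same numbers, and adjusted over all genes tested it called 211 higher and 115 lower. With the total of the table as library size it called 253 higher and 356 lower, so the share of calls that were higher went from 54.9% to 41.5%. That scaling sets the total of genes chosen as changed equal between libraries, so it can shift directions by construction.

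**Figure D1:**
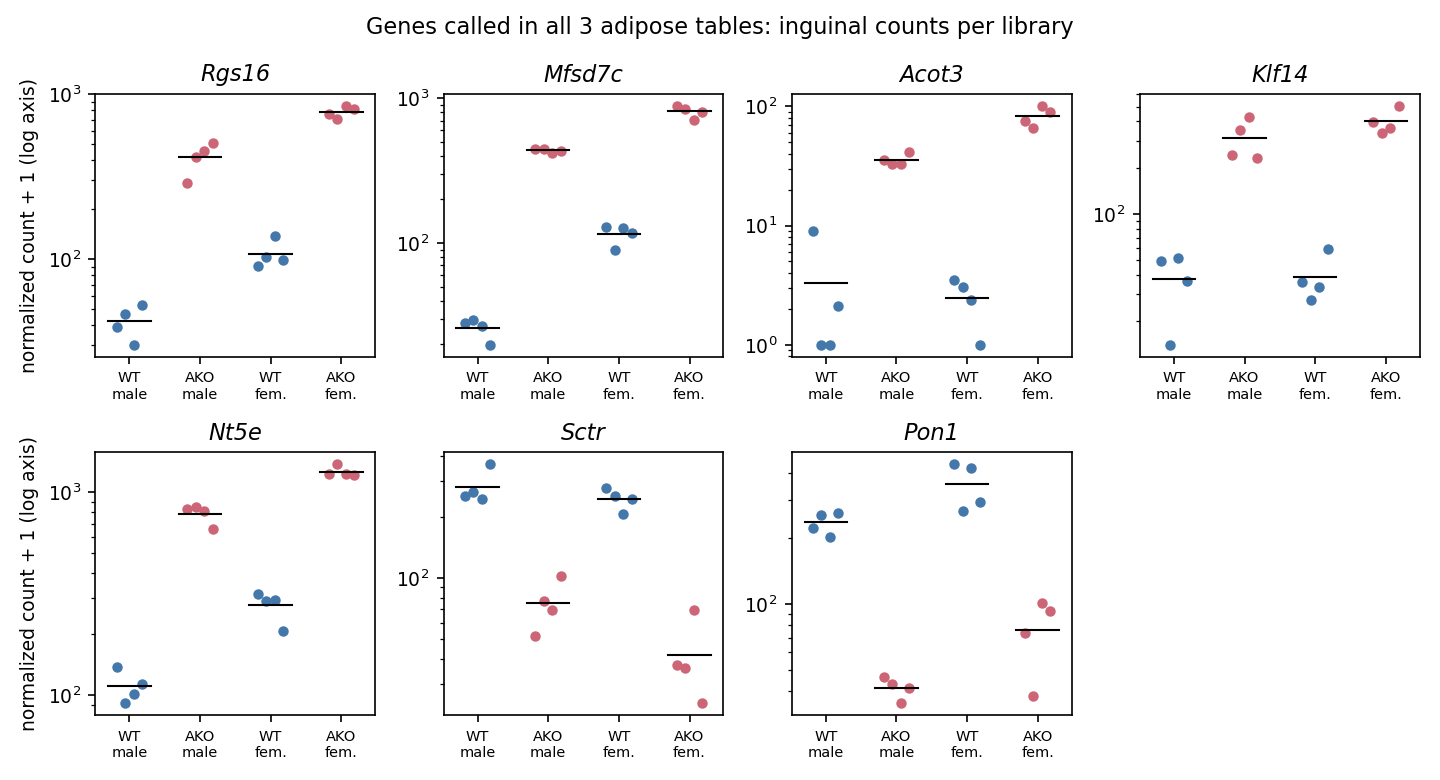
Normalized counts per library, plus 1, on log axes, for genes called in one direction in all 3 adipose tables. Points are the 4 libraries of each group in inguinal fat and lines their means. For Mfsd7c the male AKO libraries sit between 419 and 448 normalized counts and the male WT libraries between 18.8 and 28.4.

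The sexes were compared to ask whether inguinal fat responded alike in males and females. Of the genes called in both, 290 in number, all 290 changed in the same direction, 200 higher and 90 lower in AKO. From each table's own split of directions 50.3% would be expected to match (exact two-sided binomial test, p = 2.99e-87). The test counts genes as independent trials, so its p does not measure the spread between mice. Independent lists of these sizes would share 19.7 genes higher and 14.3 lower among the genes tested. The 2 sexes share no libraries. By the labels their animal numbers lie in separate ranges, so sex cannot be told apart from a difference between the sets of mice. Fold changes from the edgeR fits correlated across these genes with a Pearson r of 0.95 and a Spearman coefficient of 0.94, where genes are not independent replicates. The interaction of sex and genotype passed an adjusted p of 0.05 for 5 of the 290 genes. These genes were chosen for being called in both sexes. Genes called only in males, such as Peg3, or only in females, such as Kcnj15, were not tested. The agreement and the count of 5 therefore do not cover the whole response of either sex. Mfsd7c rose by 4.14 in males and 2.84 in females on the log2 scale (difference 1.30 ± 0.20 SE, adjusted p = 0.00094). Srgap3 (2.61 and 1.40, adjusted p = 0.0189), Fads1 (1.54 and 0.91, adjusted p = 0.0252) and Zim1, an imprinted zinc-finger gene (3.73 and 1.35, adjusted p = 0.0462), rose more in males. Rgs7 fell less in males (-0.58 against -1.31, adjusted p = 0.0369). Zim1 was named after its value was seen, and it had 18 raw counts over the 4 male WT libraries (lowest 0), so its fold in males rests on WT values near the floor. The median standard error of the difference was 0.17 and the smallest difference that passed was 0.64 (Fads1), so the other genes are not shown to respond alike. The count of 5 went to 3 with TMM scaling, to 9 with DESeq2, and to 2 without male WT replicate 3, male AKO replicates 1 or 3, female WT replicate 1 or female AKO replicates 1 or 2, and to 3 without female WT replicate 2.

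**Figure D2:**
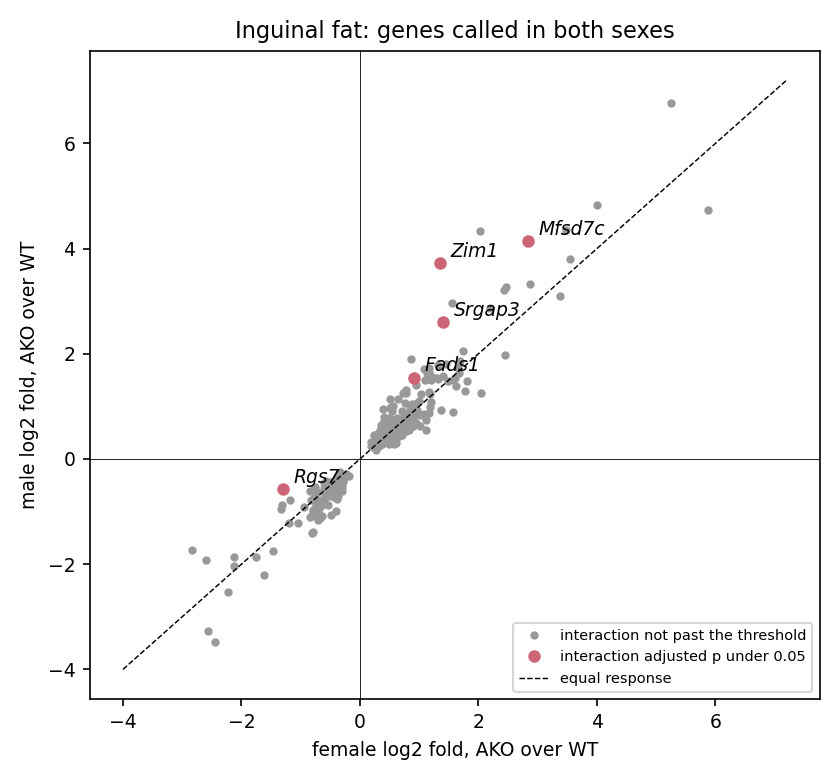
Log2 fold of AKO over WT in female (horizontal axis) and male (vertical axis) inguinal fat for the 290 genes called in both, from the edgeR fits. All points lie in the quadrants of equal direction, and the 5 genes with an interaction adjusted p under 0.05 are named.

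In male perigonadal fat, every value is from the authors' deposited table. In the authors' deposited table the largest rise was in Acot3, an acyl-CoA thioesterase gene, at 22.2-fold (log2 fold 4.47 ± 0.24 SE, adjusted p = 1.35e-75). The vitamin D receptor gene Vdr rose 9.14-fold, Rgs16 8.91-fold, Mfsd7c 8.33-fold, Nt5e 8.02-fold and Fam134b 7.54-fold in the authors' deposited table. Frmd3, Srgap3, the cell adhesion gene Ncam1 and Klf14 followed there with log2 folds of 2.75, 2.72, 2.62 and 2.59. Among the falls in the authors' deposited table, Rprml had a log2 fold of -2.07 ± 0.26, Eppk1 -1.85 ± 0.23, Net1 -1.83 ± 0.20, the growth factor gene Nrg4 -1.74 ± 0.18 and Slc2a13 -1.72 ± 0.18. Krt79, Cox8b, Sctr, Poln and Pck1 fell there by 1.68, 1.62, 1.59, 1.53 and 1.53. Pck1 encodes phosphoenolpyruvate carboxykinase and had a mean of 53978 normalized counts. Reads of Acot3 can be shared with its neighbouring thioesterase paralogs, so its values and those of Acot2 are uncertain.

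All 11 called triglyceride storage genes fell in perigonadal fat, against 51.4% of the other called genes higher (Fisher's exact test, two-sided, p = 0.000375, adjusted p = 0.00526). They included Pck1, Vldlr (log2 fold -1.27 ± 0.15 SE), the lipid droplet genes Cidec (-0.55 ± 0.08) and Cidea (-1.60 ± 0.28), Dgat2 and Plin2 in the authors' deposited table. The 6 storage genes with at least a 1.5-fold change all fell too, but the list then did not pass (adjusted p = 0.274). Of the 13 oxidation and thermogenic genes 11 fell (p = 0.0111, adjusted p = 0.0777), among them Cox8b and Acadl (-0.62 ± 0.11), while Acot2 rose 2.95-fold in the authors' deposited table. All 4 lipolysis genes fell (adjusted p = 0.201): the authors' deposited table gives Pnpla2 a log2 fold of -0.68 ± 0.08, Adrb3, the beta adrenergic receptor gene of adipocytes, -0.70 ± 0.18, the hormone-sensitive lipase gene Lipe -0.37 ± 0.07 and Mgll -0.33 ± 0.09. All 4 progenitor and mesothelial markers fell (adjusted p = 0.201), namely Krt19, Lrrn4, Cd55 and Dpp4. All 3 called genes of the growth hormone list rose (adjusted p = 0.5), with Socs2 at 3.94-fold and the prolactin receptor gene Prlr at 3.88-fold in the authors' deposited table. Macrophage markers were 5 higher, such as Atp6v0d2 (2.50-fold) and Cd68 (1.5-fold) in the authors' deposited table, and 2 lower (adjusted p = 0.704). Matrix genes were 6 higher, including Tnc (2.64-fold) and Col6a1 (1.59-fold) in the authors' deposited table, and 2 lower, Lamb3 and Timp4 (adjusted p = 0.505). Growth factor genes were 8 higher, including Igf2 (2.41-fold) and Angpt1 (1.87-fold) in the authors' deposited table, and 5 lower, including Nrg4 and Fgf1 (adjusted p = 0.72). Insulin signalling genes were 6 higher, such as Akt1, and 3 lower, such as Pygl (adjusted p = 0.71). Fatty acid synthesis genes were split 3 and 3 (adjusted p = 1): Fads1 rose 2.45-fold and Aacs, Acacb and Srebf1 fell in the authors' deposited table. Adipocyte identity genes (Nrg4, Lipe and Rxra) were all lower (adjusted p = 0.329) and cell cycle genes (Ccnd3, Cdkn2c and Myc) all higher (adjusted p = 0.5). The cytokine list was split 2 and 2 (adjusted p = 1), with Cxcl9 and Ccl8 among the higher and Hp among the lower genes. Epithelial markers were 1 higher (Esr1) and 2 lower (Krt7 and Krt14, adjusted p = 0.72). Lists with fewer than 3 called genes held Insig2 (cholesterol, lower), Cry1 (clock, higher), Bhlhe41 (clock, lower), Il1rl1 (lymphoid, higher) and Casq1 (muscle, lower). The authors listed 1488 genes of 13361 tested, 759 higher and 729 lower.

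Inguinal and perigonadal fat of the same males were compared to ask whether the depots changed alike. Of 499 genes called in both, 498 changed in the same direction, 253 higher and 245 lower (50.1% expected, exact two-sided binomial test, p = 7.3e-148). Independent lists would share 34.5 genes higher and 29.3 lower. The animals are shared, so the lists are not independent. The binomial test also counts genes as independent trials, so its p does not measure the spread between mice. Whether folds differ between depots was not tested. The exception was Lrrn4, a mesothelial marker, with a log2 fold of 1.48 in inguinal and -0.91 in perigonadal fat in the authors' deposited table. Across the 499 genes, the authors' folds correlated with a Pearson r of 0.93 and a Spearman coefficient of 0.93, where genes are not independent replicates. Female inguinal and male perigonadal fat shared 267 called genes, of which 260 changed in the same direction and 7, Lrrn4 among them, in opposite directions. Over all 3 adipose tables, 184 genes were called in each, 121 higher in all, 62 lower in all and 1 (Lrrn4) mixed. Genes with the largest smallest change over the 3 tables included Rgs16, Mfsd7c, Acot3, Klf14, Nt5e, the transcripts 4930480G23Rik and Gm20125, Sctr and St3gal6, a sialyltransferase gene. In the authors' deposited table, Rgs16 had log2 folds of 2.88 in male inguinal, 2.68 in female inguinal and 3.16 in perigonadal fat, and Sctr had -1.69, -2 and -1.59. In inguinal fat Acot3 had 4 raw counts over the 4 WT libraries in each sex, so its fold there rests on WT values near the floor.

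**Figure D3:**
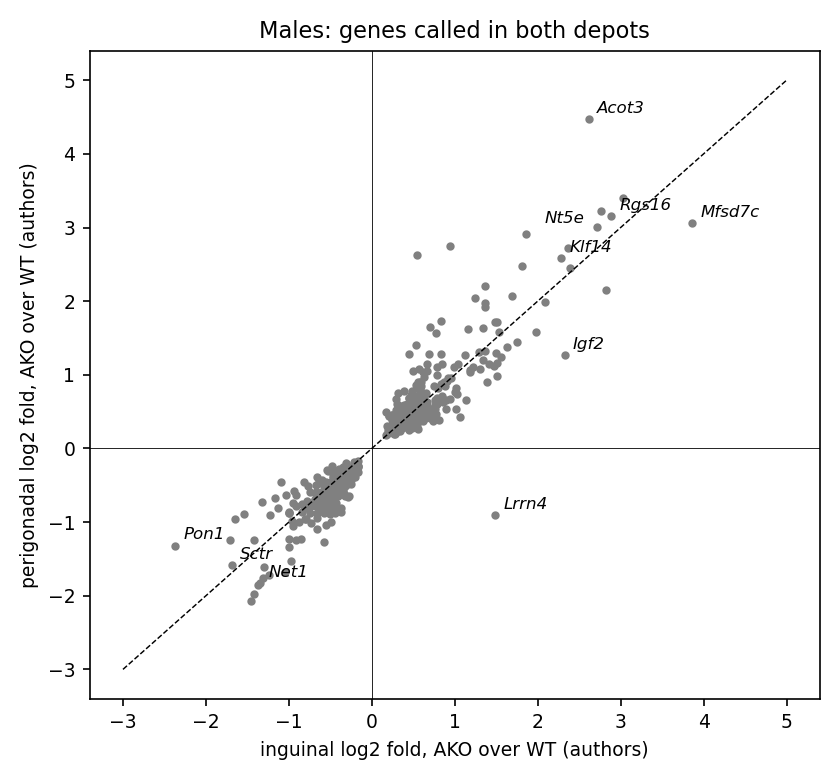
Log2 fold of AKO over WT in male inguinal (horizontal axis) and perigonadal fat (vertical axis) for the 499 genes called in both, as given in the authors' deposited table. The dashed line marks equal folds, and Lrrn4 is the gene that lies in a quadrant of opposite directions, at 1.48 and -0.91.

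In male liver, the comparison asked what differs in a tissue other than the one Cre was directed to. Few genes were listed, 9 higher and 28 lower in AKO of about 11441 tested, a number estimated from rounded values. Wdr52 rose 6.88-fold (18.2 ± 9.31 against 128 ± 36.0 normalized counts, SD, n = 4), the zinc-finger gene Zfp949 2.02-fold, the kininogen genes Kng1 1.80-fold and Kng2 1.59-fold, the helix-loop-helix gene Id2 1.78-fold, Adamts7 1.72-fold and the translation factor gene Eif4a2 1.45-fold. Ang and Tenc1 rose 1.28-fold and 1.25-fold. Among the lower genes were the nuclear receptor gene Pparg (223 ± 50 against 117 ± 36.5), the lipid droplet gene Fitm1 (log2 fold -0.90 ± 0.22 SE), the fatty acid elongase gene Elovl5 (-0.79 ± 0.15), the malic enzyme gene Me1 (-0.77 ± 0.15) and the intestinal-type fatty acid binding protein gene Fabp2 (-0.58 ± 0.10). Clstn3, Ces2e, Acaa1b, Slc16a11 and Pctp fell by 1.26, 0.59, 0.48, 0.48 and 0.47 on the log2 scale. No list had the 3 called genes needed for a test: fatty acid synthesis held Elovl5 and Me1, triglyceride storage Fitm1 and Plin2 (the latter without counts) and adipocyte identity Pparg, all lower. Kng1 and Kng2 are close paralogs whose reads may be exchanged. The 34 genes with counts all passed edgeR's test adjusted over the list alone, 9 higher and 25 lower. Adjusted over all genes tested, 3 passed (Wdr52, Kng1 and Id2, adjusted p = 0.034 each) and no lower gene did. That fit held only the 34 genes, so it does not replace the authors' test over all genes. In the authors' deposited table the adjusted p of the lower genes Pctp and Fitm1 was 7.24e-05 and 0.0243. The description of AKO replicate 4 names WT perigonadal fat, against its title, tissue and genotype, which were followed. TMM and median-of-ratios scaling on the 34 genes each gave 10 higher and 8 lower, a share higher of 55.6% against 26.5%. Both scalings assume that most genes are unchanged, while all 34 were chosen as changed and most were lower. They moved the median log2 fold from -0.36 to -0.04, a shift built into scaling on such genes. These counts therefore do not decide the direction of the liver calls. The liver sex-biased and the erythroid, granulocyte and mast cell lists had no called gene in any of the 4 tables.

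**Figure D4:**
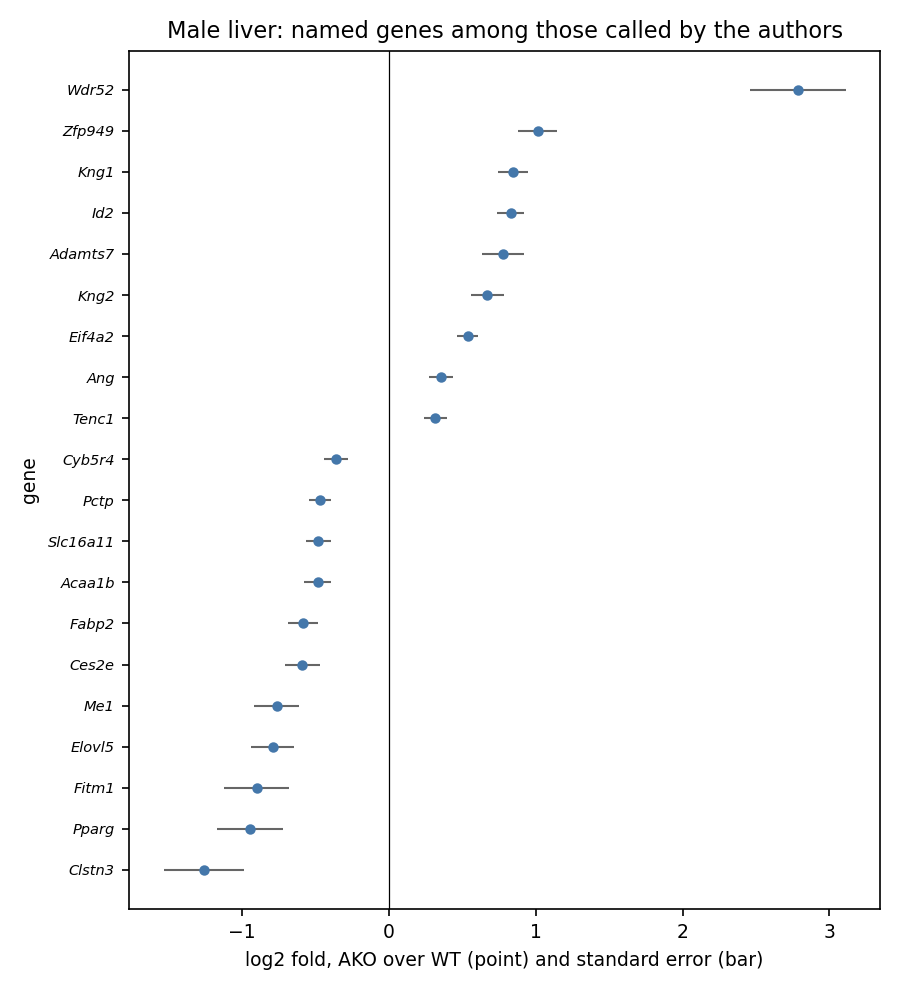
Log2 fold of AKO over WT with its standard error for the liver genes with counts that are named here, from the edgeR fit on 4 WT and 4 AKO libraries. Wdr52 is highest at 2.78 and Clstn3 lowest at -1.26.

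Liver was set beside the adipose tables to see which changes they shared. Of the liver genes 4 were called in male inguinal fat, 3 in the same direction, and 7 in perigonadal fat, all 7 in the same direction. All 5 that were called in female inguinal fat also matched in direction. With male inguinal fat 2 were higher and 1 lower in both, where independent lists would share 0.448 and 1.23. With perigonadal fat these were 2 and 5 (0.597 and 1.78 expected), and with female inguinal fat 2 and 3 (0.341 and 0.871 expected). Whether overlaps this small exceed those of independent lists was not tested. In each of the 4 tables Eif4a2 and Zfp949 were higher and Cyb5r4, named after its values were seen, was lower in AKO. In the authors' deposited table the log2 fold of Eif4a2 was 0.52 ± 0.08 in liver, 0.54 ± 0.06 in male inguinal, 0.55 ± 0.06 in female inguinal and 0.44 ± 0.15 in perigonadal fat (± SE). Elovl5 was lower in liver (-0.70 ± 0.14) and higher in male inguinal fat (0.24 ± 0.06) in the authors' deposited table. Eif4a2 (chromosome 16, 23107444 to 23114136), Kng1 (23057865 to 23082078) and Kng2 (22985854 to 23029482) lie within 200 kb of Adipoq. On chromosome 9, 4 liver genes lie within 5 Mb: Me1 (86581371 to 86695953), Cyb5r4 (87022014 to 87077774), Zfp949 (88548020 to 88571061) and Adamts7 (90163069 to 90208071). Nt5e (88327197 to 88372092) lies in the same stretch and was called in the 3 adipose tables.

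**Figure D5:**
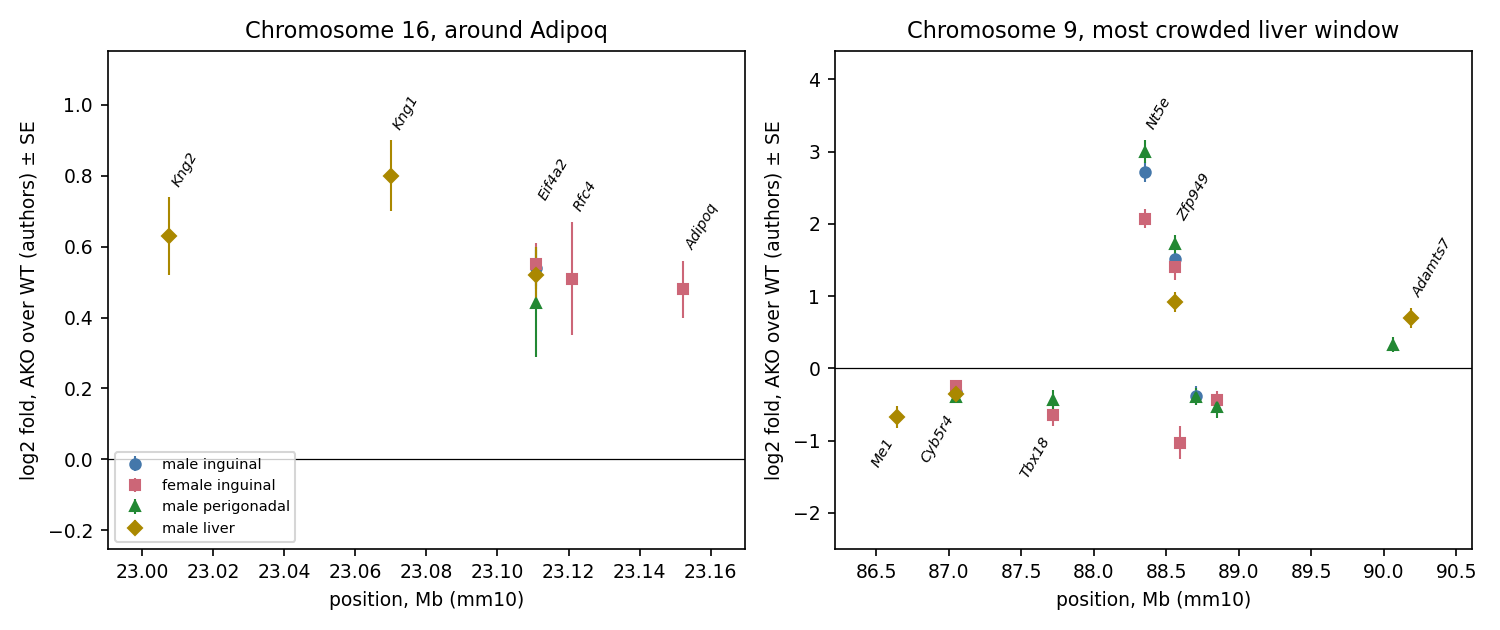
Log2 fold of AKO over WT with its standard error, from the authors' deposited table, against mm10 position for called genes around Adipoq on chromosome 16 (left) and in a 5 Mb stretch of chromosome 9 (right). Symbols mark the 4 tables, and Ctsh and gene names ending in Rik or of the form Gm and a number are not labelled. All 8 calls around Adipoq are above 0.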

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

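All tests of explanations in this part were chosen after the results were seen, apart from the interaction of sex and genotype, which was planned. The genes around Adipoq and on chromosome 9 were not planned either and were chosen after the results were seen.

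All 8 calls within 200 kb of Adipoq in the 4 tables were higher in AKO: Eif4a2 in each table, Rfc4 and Adipoq in female inguinal fat, and Kng1 and Kng2 in liver. In liver these are 3 of 37 listed genes, and none of 10000 random draws of 37 protein-coding genes placed as many there (permutation p = 0.0001, the smallest that the draws can give). Extra copies of neighbouring genes carried by the Cre transgene may account for this, if that transgene holds a long genomic stretch around Adipoq, which the labels do not state. The draws used all protein-coding genes, since the genes expressed in liver are not held, and Kng1 and Kng2 may exchange reads. An effect of the deletion on these genes stays open.

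The liver list was also crowded on chromosome 9, where 4 genes lie within 5 Mb, a number reached in 164 of 10000 random draws (permutation p = 0.0165). A chromosome 9 segment that travels with the Cre transgene may account for it, such as an insertion site or a stretch from another strain. The genes called there in both liver and adipose tissue, Zfp949 and Cyb5r4, kept their directions. The same stretch held 6 called genes in female inguinal fat (1.1 expected), 7 in perigonadal fat (2.2) and 4 in male inguinal fat (1.6). The draws and the expected numbers used all protein-coding genes, since the genes expressed in each tissue are not held. The called numbers in fat were not limited to protein-coding genes. They included 9430037G07Rik and 9330159M07Rik in females, 9330159M07Rik and Gm2382 in perigonadal fat, and Gm2382 in male inguinal fat. The excess in fat may therefore be overstated, and in male inguinal fat 4 against 1.6 does not show an excess. The 3 genes called in all 4 tables (Eif4a2, Zfp949 and Cyb5r4) had liver log2 folds 1.02 times the mean adipose folds in the median (1.02, 0.59 and 1.11), but they were chosen for being called in liver, so this does not decide whether deletion of Bcl6 acted within the adipocytes alone. An effect that reaches liver from fat stays open. Nt5e lies in this stretch and was one of the largest changes in fat, so whether its rise follows from loss of Bcl6 is open too.

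Bcl6 counts were higher in every female library labelled AKO than in every WT library. An exchange of WT and AKO labels in the females is argued against, since 0% of the 290 genes called in both sexes changed in opposite directions. Deeper AKO libraries are argued against as well: the ratio of Bcl6 between the 2 shallowest AKO and the 2 deepest WT libraries was 2.48. Reads from exons left in place after recombination are argued against as the whole cause, since they would keep the count over the gene at the WT level at most, and the log2 fold was 1.16 ± 0.12 SE. Higher expression of the locus stays open, and whether its transcripts lack the deleted exons was not tested, since no counts per exon are held. The RNA is of fat tissue and not of adipocytes alone, so which cells gave the Bcl6 reads was not tested either.

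Among the 290 genes called in both sexes, the response of 5 differed between males and females by a test of the interaction. Sex could not be told apart from the set of mice. Male minus female log2 folds were 1.30 for Mfsd7c, 0.64 for Fads1, 1.2 for Srgap3, 2.37 for Zim1 and 0.73 for Rgs7. Of 100 arrangements of the sex labels tested with limma, the real one included, 1 (the real one) gave as many genes. The real labels gave 4 genes with limma and the highest other arrangement gave 2. For the AKO and WT comparisons, the real split gave 1072, 790 and 34 genes for male inguinal fat, female inguinal fat and liver. The highest other of 35 splits gave 0 in each and 1 split, the real one, gave as many. These splits and arrangements decide nothing, since the genes were listed because they differ between the real groups.

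Single libraries stood apart in 16 of 306 groups of 4 tested (5.23%), where chance gives 5%. In male inguinal fat, AKO replicate 1 had 1099 normalized counts of Cspg4 (others 963 to 984), WT replicate 1 had 8.05 of Acot3 (others 0 to 1.11) and WT replicate 1 had 5082 of Net1 (others 6585 to 6818). In female inguinal fat, AKO replicate 3 had 222 of Acsm3 (others 151 to 161), 5994 of Akt1 (others 5028 to 5175), 7371 of Fads1 (others 6159 to 6305) and 17196 of Igfbp4 (others 13910 to 14443). Female AKO replicate 1 had 1804 of Kcnj15 (others 2329 to 2398), AKO replicate 2 had 1373 of Nt5e (others 1214 to 1230) and AKO replicate 4 had 1848 of Trps1 (others 1180 to 1219). Female WT replicate 3 had 8868 of Aacs (others 7504 to 7606) and WT replicate 4 had 785 of Plin5 (others 433 to 463). In liver, AKO replicate 2 had 237 of Slc16a11 (others 200 to 206), AKO replicate 3 had 275 of Zfp949 (others 213 to 216) and WT replicate 1 had 5590 of Kng2 (others 4730 to 4753). The size factor of liver WT replicate 2 was 2.2 (others 0.603 to 0.784).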

How the results depend on the processing

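Adjusting p over all genes tested was chosen after seeing the data, and the other alternatives were planned. Over 150 pairs of a gene named here and a table, 2446 of 2550 alternative values kept direction and side of the threshold, 104 fell short of it and 0 reversed. Of the 104, 44 fell short of a 1.5-fold change, 36 when p was adjusted over all genes tested, 10 with median-of-ratios scaling, 6 with TMM and 5 with the total of the table. Outside the adjustment over all genes, p was adjusted over the list alone, whose genes were chosen as called, which favours values that hold. The adjustment over all genes tested used fits that held only the called genes, so it does not replace the authors' test. With it, calls were 366 higher and 285 lower in male inguinal fat, 211 and 115 in female inguinal fat and 3 and 0 in liver. With at least a 1.5-fold change they were 220 and 132, 189 and 191, and, for lower liver genes, 10. The total of the table as library size gave 253 higher female genes. TMM and median-of-ratios scaling gave 8 lower liver genes each. These scalings moved the median log2 fold by -0.21 (total, female), -0.16 (median of ratios, female) and 0.32 (TMM and median of ratios, liver). They treat the called genes as unchanged on the whole, although these were chosen for change, so such shifts can arise by construction. In females 6 of 790 genes changed sign with the total and 0 with median of ratios. In liver 6 of 34 changed sign with TMM and 6 with median of ratios. The interaction count of 5 became 3 with TMM and 9 with DESeq2. Leaving out 1 library gave 566 to 569 higher and 496 to 503 lower genes in males, 430 to 434 and 352 to 356 in females, 9 and 25 in liver, and 2 to 7 genes for the interaction. In perigonadal fat the authors' adjusted p under 0.01, under 0.001 and a 1.5-fold change left 470, 300 and 256 higher and 432, 286 and 264 lower genes. The same settings left 175, 123 and 120 genes called in one direction in both sexes, 307, 204 and 149 in both male depots, and 1, 1 and 0 gene lists past the threshold. The cause was not tested where neither a stricter threshold nor scaling on the called genes gives it by construction. The replicate number as a block gave 569 and 503, 433 and 354, and 9 and 25 genes, and 7 for the interaction. Deviations of same-numbered libraries correlated at 0.26, 0.15, 0.15 and 0.07 in male inguinal fat, at -0.30, 0.00, 0.18 and -0.15 in female inguinal fat and at -0.36, 0.08, 0.14 and -0.58 in liver, and the own number gave the highest correlation for 2, 1 and 1 of 4 replicates. No table had all pairs over 0.1, so the numbers were not taken to pair the samples, although in male inguinal fat all 4 were positive and liver animal numbers are adjacent within each replicate number. Depth limits genes with few counts, such as Gpr179 and Acot3 in WT.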

Other observations

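The test of epithelial markers was chosen before its result was seen, and the test of imprinted genes and its gene list after several such genes had been seen among the calls.

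Whether imprinted genes are higher in AKO as a set is a hypothesis that these tables cannot decide, since the list was written after such genes had been seen among the calls. In male inguinal fat 10 of 10 called members of a list of imprinted genes were higher (Fisher's exact test, two-sided, adjusted p = 0.00661 over 3 tables), among them Igf2, Peg3, Zim1, Peg10, Plagl1, Grb10, Ndn and Nap1l5. In female inguinal fat 7 of 7 were higher (adjusted p = 0.0276), among them Cdkn1c, Sgce and Plagl1, and in perigonadal fat 8 of 9 (adjusted p = 0.0388), with Rian lower. Other called genes were higher in 52.6%, 54.5% and 50.8%. Peg3 and Zim1 are neighbours, so their counts may share reads, and male inguinal and perigonadal fat came from the same mice.

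A smaller share of epithelial cells in the female AKO samples may account for the lower epithelial markers (Krt7, Krt8, Csn3, Trps1 and Cldn7). After group means were removed, the mean correlation between these 5 markers was 0.46, at the 99.3 percentile of 10000 random sets of 5 genes from the same table (median -0.01, 95th percentile 0.28). The inguinal pad of females holds mammary tissue, and a dissection that took more or less of it, or a change in that tissue, would both give this pattern.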
